A study of Homo sapiens with 8 samples.

How the data were processed

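The series holds RNA-seq of total RNA from MCF7 cells, wild type or labelled as an RB knockout, under DMSO or palbociclib, with 2 libraries in each of 4 groups. Each library came as 1 file of deposited counts, whole reads per gene, made with Trimmomatic, TopHat2, SAMtools and HTSeq on build hg38, per the submitters' processing notes. The tools' versions, their settings, the strandedness of the libraries, the means of selecting RNA and the annotation release are not given in the sources used here. The values were not normalised before deposit, as far as they show: they are whole numbers with a different total in each file. Groups were taken from the genotype and agent labels and from the sample titles, which also name the replicates a2 and b2.

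Each file had 58037 rows under the same names in the same order. Of these rows, 2064 shared 294 names with another row and 28 carried a symbol that spreadsheet software had turned into a date. Such rows stayed in library sizes and in the tests but were never named as genes. No summary row for unassigned reads was present. Total counts were 26969016 and 32079470 (wild type, DMSO), 30495047 and 28951315 (wild type, palbociclib), 29488689 and 28694183 (knockout, DMSO), and 22576359 and 23693777 (knockout, palbociclib). A chi-square statistic per degree of freedom between the libraries of a group lay between 11.0 and 29.0, far above the value of 1 that sampling alone gives, so no library was a second copy of another. As strand was not stated, reads of a gene and of an antisense or overlapping gene could not be told apart. Of 130 genes chosen for naming, of which the text prints a part, 60 have exons overlapped by another gene in GENCODE release 29, among them RRM2, KIF20A, KIF4A, PLK1, FANCI, RAD51, CCNE2, CDK4, CDK6, IGFBP5, MX1 and SLC27A6. Genes with close paralogs or pseudogenes, such as UGT2B15, HLA-F, the histone genes and the ribosomal protein genes, are uncertain in the same way. Positions were taken from that release on GRCh38 by symbol, and all 130 symbols matched a single gene. The files themselves give no positions.

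Levels in CPM are deposited counts divided by the effective library size, as edgeR's cpm function gives them. Tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr on the 4 groups with a minimum count of 10 and a minimum total count of 15, and glmQLFit with glmQLFTest on a design with 1 mean per group. The filter kept 16620 genes with 99.94 percent of all counts. All 8 libraries entered 1 fit, which left 4 residual degrees of freedom per gene beside a prior of 12.6, and the biological coefficient of variation was 0.102. The 5 comparisons were palbociclib against DMSO in wild type and in the knockout, the difference between these effects, and knockout against wild type under DMSO and under palbociclib. P-values were adjusted by Benjamini and Hochberg over all genes tested, and genes under 0.05 were called with no minimum fold. The standard error of a log2 change was derived from the F statistic.

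Before the data were examined, 26 gene lists with 773 entries were fixed, together with the comparisons, the tests, the alternatives and the rule for naming genes. Of the entries, 720 matched the files by current symbol and 51 by an older symbol, and 2 did not match. Lists with fewer than 5 tested genes were not tested, which left 25 lists and 125 list tests. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over all lists and comparisons. With the correlation estimated for each list, 13 of the 56 called tests remained past the threshold, and with 2 libraries per group that estimate is itself imprecise. Each list given below with an adjusted p at an estimated correlation was called by camera at the preset correlation. fry was run beside it, with its directional p for whether the genes of a list move on balance 1 way and its mixed p for change in either direction; neither compares a list with other genes. A count given as adjusted over the list alone used the same gene p-values adjusted within that list.

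The rule for named genes took RB1 and any member of the RB and CDK list. For each comparison it took the 8 largest changes in each direction among called genes with a symbol, a mean of at least 2 CPM and no overlap between the libraries of the groups compared. The condition of no overlap was not asked of the difference between the effects. The rule also took up to 4 members of each list with the smallest p. The text prints a part of these, and its counts of named genes cover all 130 chosen. Genes outside the rule are said to have been chosen after their values were seen.

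The alternatives were RLE, upper quartile and total-count scaling, no filter on low counts, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a robust prior, fits of only the 4 libraries compared, the replicate letter as a block, a minimum log2 change of 1, and leaving out each of the 8 libraries in turn. In the last, 1 group has a single library, which is assumed to vary like the others.

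The test was tried on simulated counts for 16620 genes, drawn from the real means and library sizes, in which 200 genes were changed. For palbociclib in wild type it recovered 32.8 percent of 1.5-fold, 70.1 percent of 2-fold and 98.5 percent of 4-fold changes, and 7.59 percent of its calls were false. For palbociclib in the knockout it recovered 46.3, 76.1 and 90.9 percent, and 5.96 percent of its calls were false. Both simulations used the same means, averaged over all 8 libraries, so the gap between them says nothing about the genotypes. The real comparison in wild type called 4742 genes, far more than the 200 changed here. These recoveries are therefore not those of the real comparisons. These false shares lie above the nominal 5 percent. A requirement of 80 percent recovery, set first for changes of 2-fold and more, was missed at 2-fold in both simulations and was then replaced by limits on bias and on false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.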

Results

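RNA was sequenced from MCF7 cells, an estrogen receptor positive breast cancer line, in a wild type form and in a form labelled as an RB knockout. RB, the product of RB1, holds back E2F transcription factors until cyclin D kinases phosphorylate it, and palbociclib inhibits those kinases, CDK4 and CDK6. Each form was kept for up to 48 hours in 0.1 percent DMSO or in 250 nM palbociclib with the same DMSO, which gave 4 groups of 2 libraries, 8 libraries in all. The libraries held 22576359 to 32079470 counted reads each, and 16620 genes had enough counts to be tested. The design asks how far the response to the drug depends on RB. The labels name the libraries of each group a2 and b2 without saying whether they were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The first principal component of log expression held 59.8 percent of the variance and set the wild type palbociclib libraries, at 73.0 and 73.9, apart from the other 6, which lay between -40.4 and -11.8.

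RB1 itself was lower in the knockout libraries than in the wild type libraries under both treatments. RB1 lies on chromosome 13 of GRCh38 from 48303726 to 48599436. In wild type cells it stood at 58.56 and 71.57 CPM (counts scaled by effective library size) under DMSO and at 46.77 and 57.12 CPM under palbociclib. In the knockout it stood at 16.45 and 15.99 CPM under DMSO and at 15.26 and 22.45 CPM under palbociclib, which left 24.9 percent and 36.3 percent of the wild type means. The log2 change from wild type to knockout was -2.004 (SE 0.17, edgeR adjusted p = 1.29e-06) under DMSO and -1.46 (SE 0.17, adjusted p = 5.16e-06) under palbociclib. Reads counted per gene do not show whether the remaining RB1 RNA encodes an intact protein. Palbociclib gave no called change of RB1 in wild type (log2 change -0.33, adjusted p = 0.147) or in the knockout (0.22, adjusted p = 0.537), and the difference between these effects, -0.55, was not called either (adjusted p = 0.222). Without replicate a2 of the knockout under palbociclib, the wild type change (-0.33, adjusted p = 0.049) and the difference (-0.83, adjusted p = 0.0107) passed the threshold.

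In wild type cells palbociclib lowered genes of DNA synthesis and cell division, some of them to under 1 CPM. RRM2, a subunit of the enzyme that makes deoxyribonucleotides (chromosome 2, 10120698 to 10131419), fell from 358 ± 27.6 CPM to 0.643 ± 0.297 CPM (SD, n = 2 per group), a log2 change of -9.10 (SE 0.22, edgeR adjusted p = 5.61e-14). KIF20A, a kinesin of cytokinesis (chromosome 5, 138178719 to 138187715), fell from 139 ± 5.22 to 0.319 ± 0.162 CPM, a log2 change of -8.76 (SE 0.22, adjusted p = 5.61e-14). IFIT1, an interferon-induced inhibitor of viral translation (chromosome 10, 89392546 to 89406486), rose from 3.94 ± 1.18 to 21.0 ± 5.31 CPM, a log2 change of 2.43 (SE 0.25, adjusted p = 1.02e-06).

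All 50 tested members of the DNA replication list were lower, also when adjusted over the list alone, with a median log2 change of -2.33, or 5.04-fold. Examples were thymidine kinase TK1 (-5.26), the replication initiation factor MCM10 (-6.83) and CDC45 (-4.89), part of the replicative helicase. All 50 members of the mitosis list were lower as well, likewise over the list alone, with a median log2 change of -5.10, or 34.2-fold. They included the mitotic kinases AURKB (-7.27) and PLK1 (-6.40), the survivin gene BIRC5 (-7.08) and KIF4A (-7.33), a chromosome-bound kinesin. Of the 32 tested genes of homologous recombination and the Fanconi pathway, 32 were lower over all genes and over the list alone, among them the recombinase RAD51 (-3.92), the nuclease EXO1 (-5.09) and FANCI (-3.60). Camera called these 3 lists with a preset correlation, and with an estimated correlation their adjusted p-values were 0.0028, 0.0032 and 0.016.

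Within the RB and CDK list, 20 of 34 genes were lower and 6 higher (21 and 6 adjusted over the list alone), with an adjusted p = 0.015 with an estimated correlation. The lower genes included E2F1 (-2.77), E2F7 (-5.19), E2F8 (-5.27), the RB relative RBL1 (-2.68) and the CDK2 partners CCNE2 (-5.32) and CCNE1 (-1.21). CDK4, one of the drug's targets, was lower by a smaller amount (-0.75). The other target, CDK6 (chromosome 7, 92604921 to 92836594), rose from 17.4 ± 2.18 to 43.9 ± 4.29 CPM, a log2 change of 1.33 (SE 0.15, edgeR adjusted p = 3.21e-06). Its inhibitor CDKN2B (chromosome 9, 22002903 to 22009363) rose from 15.6 ± 0.205 to 38.6 ± 1.05 CPM (1.31, SE 0.13, adjusted p = 5.46e-07), and cyclin D1, CCND1, rose by 0.71. CDKN1A, the p21 gene, stood at 203 ± 20.2 and 192 ± 17.6 CPM and was not called (adjusted p = 0.71).

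Of 39 interferon-response genes, 26 were higher and none lower in wild type (28 adjusted over the list alone), with a median of 0.88. Camera called this list at the preset correlation (adjusted p = 1.67e-08) but not with an estimated correlation (adjusted p = 0.55). OAS1, a sensor of double-stranded RNA, rose by 1.51, SAMD9 by 1.47 and the RNA sensor gene listed as DDX58 by 1.48. Of 21 genes of class I antigen presentation, 10 were higher (10 over the list alone, adjusted p = 0.60 with an estimated correlation), such as the peptide transporter TAP1 (0.75) and HLA-F (1.08). That preset call ended without replicate a2 under palbociclib (adjusted p = 0.0706). Among 35 lysosomal genes, 19 were higher and 1 lower (23 and 1 adjusted over the list alone, adjusted p = 0.34 with an estimated correlation), including the hydrolases GNS (0.82) and ARSA (0.92). Of 26 luminal epithelial genes, 7 were higher and 1 lower (8 and 1 over the list alone, adjusted p = 0.63 with an estimated correlation), with keratin KRT19 up by 0.68. This call ended without replicate b2 under DMSO (adjusted p = 0.205) or a2 under palbociclib (adjusted p = 0.0505), with total counts (adjusted p = 0.0541) and with a filter of 1 CPM (adjusted p = 0.0503). Of 36 genes of ribosome biogenesis, 14 were lower (16 over the list alone, adjusted p = 0.41 with an estimated correlation), such as NOP56 (-0.72) and LYAR (-1.22). The mitochondrially encoded genes were higher in 11 of 13 cases (11 over the list alone, adjusted p = 0.68 with an estimated correlation), among them MT-CO1 (0.72) and MT-ND3 (0.66). The share of all counts from the mitochondrial genome was 1.80 and 1.67 percent under DMSO and 2.54 and 3.15 percent under palbociclib, so it moved with each of these groups. Estrogen-response genes had no common direction, with 6 higher and 6 lower of 40 (6 and 6 over the list alone), a median of 0.05 and a mean of -0.02.

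**Figure D1:**
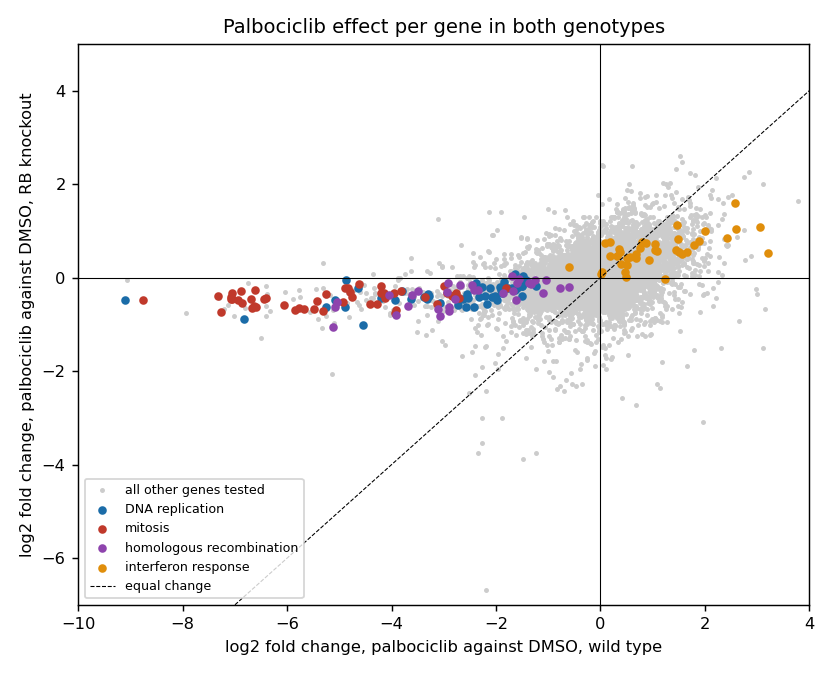
Log2 change after palbociclib in wild type MCF7 cells (horizontal axis) against that in RB knockout cells (vertical axis) for the 16620 genes tested, 1 point per gene, with members of fixed lists in colour. The DNA replication and mitosis genes lie far to the left, with list medians of -2.33 and -5.10 in wild type against -0.39 and -0.43 in the knockout.

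At an adjusted p under 0.05, edgeR's quasi-likelihood test called 2254 genes higher and 2488 lower after palbociclib in wild type cells, and 532 and 970 of these changed at least 2-fold. The called genes were 28.5 percent of all genes tested, so a list with about that share called, such as the luminal list, does not stand out by its count. The higher share of the calls was 47.5 percent, against 54.6 percent with upper quartile scaling and 39.1 percent with total counts, so which direction held more genes depends on the scaling. Leaving out wild type replicate b2 under DMSO left 1368 genes higher, leaving out replicate a2 under palbociclib left 1233 higher and 1643 lower, and leaving out replicate b2 under palbociclib left 1345 and 1603. Of 59 named genes called in this comparison, 57 kept the call in every leave-out.

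In RB knockout cells a part of the cell-cycle genes was lower under palbociclib. MCM10 went from 69.2 ± 3.11 to 37.4 ± 1.25 CPM, a log2 change of -0.89 (SE 0.13, edgeR adjusted p = 0.000817). ORC1, a subunit of the complex that marks replication origins (chromosome 1, 52372829 to 52404459), went from 33.7 ± 0.271 to 16.6 ± 0.335 CPM, a log2 change of -1.02 (SE 0.14, adjusted p = 0.000764). CDK6 and CDKN2B rose, CDK6 from 16.3 ± 1.33 to 36.7 ± 5.85 CPM (1.17, SE 0.15, adjusted p = 0.000343) and CDKN2B from 9.54 ± 0.28 to 22.8 ± 0.993 CPM (1.26, SE 0.13, adjusted p = 0.000116). The growth factor gene TGFB2 (chromosome 1, 218346235 to 218444619) rose from 5.86 ± 0.614 to 22.5 ± 2.26 CPM, a log2 change of 1.94 (SE 0.17, adjusted p = 5.40e-05). RRM2, chosen here after its values were seen, stood at 337 ± 14.8 and 242 ± 1.69 CPM and was not called (log2 change -0.48, adjusted p = 0.0592), though DESeq2 (adjusted p = 0.00715), limma-voom (adjusted p = 0.0498) and a fit with no filter (adjusted p = 0.0108) called it.

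Of the 50 DNA replication genes, 11 were lower in the knockout and none higher (28 adjusted over the list alone), with a median log2 change of -0.39 and an adjusted p = 0.035 with an estimated correlation. Of the 50 mitosis genes, 18 were lower (40 over the list alone), with a median of -0.43 and an adjusted p = 0.12 with an estimated correlation, and MYBL2, an activator of mitotic genes, changed by -0.75. Of 32 recombination genes, 9 were lower (15 over the list alone), with an adjusted p = 0.23 with an estimated correlation. The RB and CDK list was not called by camera, with 2 genes higher and 2 lower of 34 (3 and 2 over the list alone), a median of -0.07 and a mean of 0.002, and CCNE1 stood at 21.9 ± 3.10 and 31.7 ± 5.70 CPM (log2 change 0.53, adjusted p = 0.0571). CCNE1 was called by DESeq2 (adjusted p = 0.0357), with no filter (adjusted p = 0.0249) and without knockout replicate b2 under palbociclib (0.70, adjusted p = 0.0135).

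Of 39 interferon-response genes, 11 were higher and none lower in the knockout (27 adjusted over the list alone), with a median of 0.56 and an adjusted p = 0.34 with an estimated correlation. SAMD9 changed by 1.12, a call that was lost without replicate b2 of the knockout under DMSO (0.88, adjusted p = 0.0585). Antigen presentation genes were higher in 4 of 21 cases and lower in 1 (6 and 1 over the list alone, adjusted p = 0.46 with an estimated correlation). The preset call ended without knockout replicate a2 under palbociclib (adjusted p = 0.165). Of 40 estrogen-response genes, 8 were lower and 1 higher (10 and 2 over the list alone, adjusted p = 0.66 with an estimated correlation). That call ended without knockout replicate a2 under DMSO (adjusted p = 0.254) or a2 under palbociclib (adjusted p = 0.708). Ribosome biogenesis genes had a median of -0.21 with 1 of 36 lower (1 over the list alone, adjusted p = 0.16 with an estimated correlation). The lysosomal list had a median of 0.13 with none of 35 genes called, over all genes or over the list alone (adjusted p = 0.46 with an estimated correlation). Its preset call ended without knockout replicate a2 under palbociclib (adjusted p = 0.0908). The mitochondrially encoded list had a median of 0.25 with none of 13 called (5 higher over the list alone, adjusted p = 0.66 with an estimated correlation), beside mitochondrial shares of 1.40 and 1.27 percent under DMSO and 1.70 and 1.89 percent under palbociclib. Its preset call ended without knockout replicate b2 under palbociclib (adjusted p = 0.0515).

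The largest increases in the knockout among genes of at least 2 CPM included GABRP, a GABA receptor subunit, which rose by 2.39 from 0.693 ± 0.0963 CPM, PGM5 by 1.87 and ALDH1A3, a retinoic acid synthesis enzyme, by 1.77. STON1, whose exons are shared with the readthrough gene STON1-GTF2A1L, rose by 1.73. edgeR called 499 genes higher and 200 lower, together 4.21 percent of all genes tested, of which 119 and 32 changed at least 2-fold. These counts moved with single libraries: 166 and 55 without knockout replicate a2 under DMSO, 104 and 19 without b2 under DMSO, 1089 and 485 without a2 under palbociclib, and 122 lower without b2 under palbociclib. Of 44 named genes called here, 28 lost the call without replicate b2 under DMSO, 14 without a2 under DMSO, and 14 kept it in every leave-out.

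The difference between the drug's effects, wild type minus knockout, was tested directly. It was largest for the genes of DNA synthesis and division. RRM2 differed by -8.62 (SE 0.26, edgeR adjusted p = 2.04e-12), KIF20A by -8.27 (SE 0.26, adjusted p = 2.53e-12) and FAM111B, a gene with a role in DNA replication, by -6.65 (SE 0.31, adjusted p = 6.00e-11). CCNE2 (chromosome 8, 94879770 to 94896678) went from 32.4 ± 5.94 to 0.809 ± 0.132 CPM in wild type and from 36.7 ± 3.69 to 45.9 ± 3.74 CPM in the knockout, a difference of -5.64 (SE 0.26, adjusted p = 6.71e-11). In the other direction, UGT2B15 (chromosome 4, 68646630 to 68670628), an enzyme of steroid glucuronidation, went from 5.04 ± 0.798 to 20 ± 0.58 CPM in wild type. In the knockout it went from 1.55 ± 0.279 to 1.84 ± 0.221 CPM, a difference between the effects of 1.73 (SE 0.29, adjusted p = 0.000756). Its reads could be shared with its close paralog UGT2B17.

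The median differences were -1.93 for DNA replication and -4.64 for mitosis, each with a camera adjusted p = 0.0028 with an estimated correlation. All 50 genes of each list had a more negative log2 change in wild type, called over all genes and over each list alone. So did 30 of 32 recombination genes (32 adjusted over the list alone, adjusted p = 0.016 with an estimated correlation) and 16 of 34 RB and CDK genes, with 1 in the other direction (18 and 1 over the list alone, adjusted p = 0.0081 with an estimated correlation). E2F7 differed by -4.82 and E2F8 by -4.44, while CDK6 (0.16, adjusted p = 0.746), CDKN2B (0.05, adjusted p = 0.917) and CCND1 (0.34, adjusted p = 0.389) were not called as different. STON1, chosen here after its values were seen, was not called as different either (0.71, adjusted p = 0.266).

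Outside the cell cycle, the effect of palbociclib was called as different between genotypes for some interferon-response genes and for no lysosomal or ribosomal protein gene. Replication-dependent histone genes had 3 of 28 higher and 3 lower, and fatty acid synthesis genes 2 of 14 lower, beside 6.46 percent of all genes called. Of 39 interferon-response genes, 4 had a higher log2 change in wild type (4 over the list alone), beside 179 of all 16620 genes. The median difference was 0.35, with a camera adjusted p = 0.80 with an estimated correlation. The preset call ended without wild type replicate a2 under palbociclib (median 0.127, adjusted p = 0.0563), knockout a2 under DMSO (median 0.187, adjusted p = 0.0822) or knockout a2 under palbociclib (median 0.257, adjusted p = 0.0639). No lysosomal gene (median 0.22, adjusted p = 0.46 with an estimated correlation) and no ribosomal protein gene (median 0.47, adjusted p = 0.69 with an estimated correlation) was called by edgeR alone, over all genes or over the list alone. PHGDH, the first enzyme of serine synthesis, differed by -2.09 and SLC7A5, an amino acid transporter, by -0.98. TM7SF2, a sterol reductase gene whose exons are overlapped by VPS51, differed by 0.95.

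edgeR called 179 genes with a higher log2 change after palbociclib in wild type than in the knockout. Another 894 had a lower one, that is more negative or less positive. The count of 179 became 94 without wild type replicate b2 under DMSO, 56 and 93 without wild type a2 or b2 under palbociclib, 70 and 84 without knockout a2 or b2 under DMSO, and 473 without knockout a2 under palbociclib. Across the 16620 genes, 362 were higher in both genotypes, where independent lists would share 67.7, and 160 were lower in both against 29.9 for independent lists. Another 7 were called in opposite directions. The log2 changes correlated across genes with Pearson's r of 0.418 and Spearman's rho of 0.475, where genes are not independent replicates and the comparisons share no library. Of the 2488 genes lower in wild type, 861, or 34.6 percent, also had a difference called by the test in the lower direction, and for the others the test left open whether the effects differed.

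**Figure D2:**
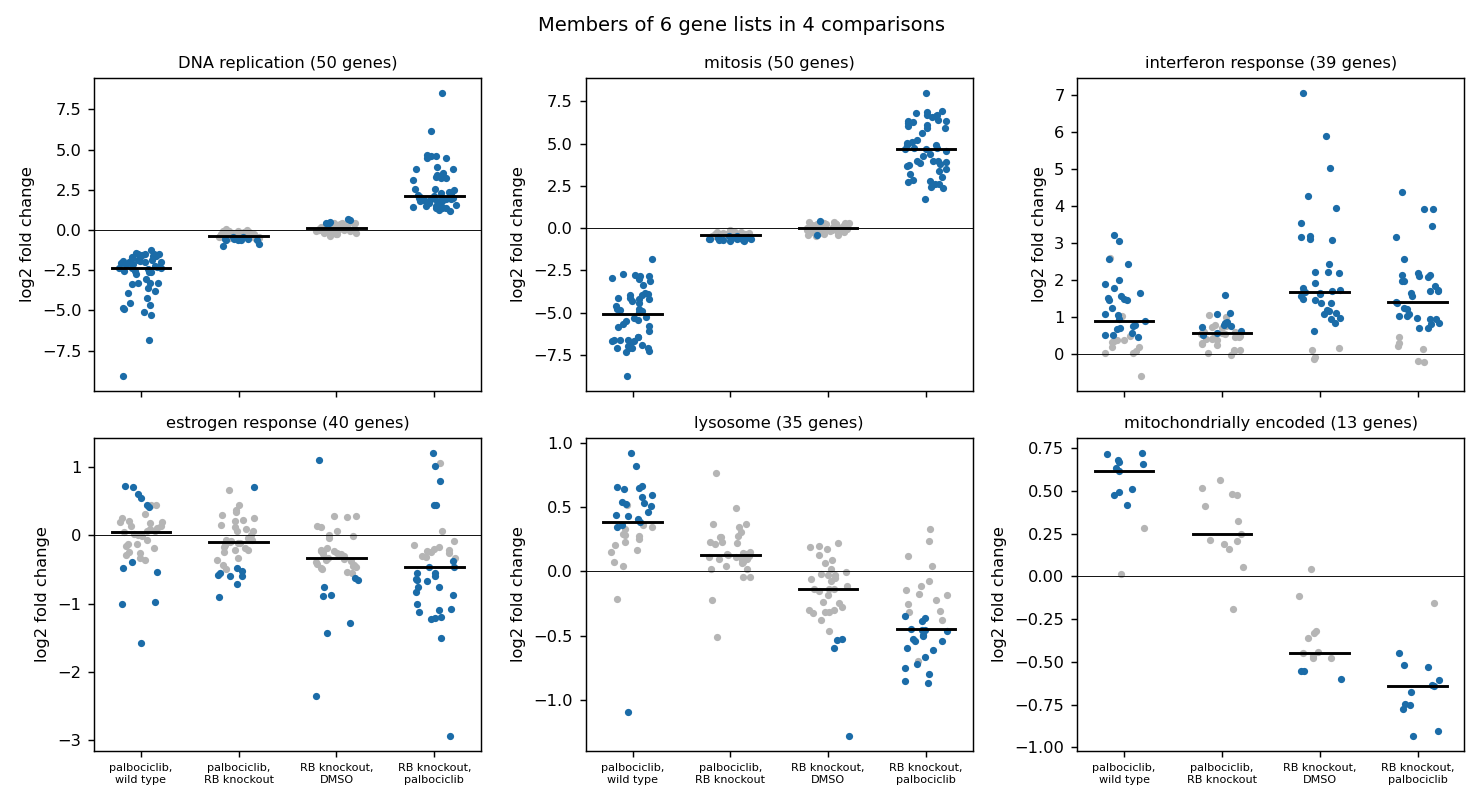
Log2 change of each tested member of 6 fixed gene lists in 4 comparisons, 1 point per gene, blue where edgeR's adjusted p was under 0.05 and grey otherwise, with a bar at the list's median. The interferon-response medians are 0.88, 0.56, 1.67 and 1.42 from left to right, and the mitosis medians are -5.10, -0.43, 0.04 and 4.70.

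Under DMSO, the genes that differed most between knockout and wild type included members of the interferon-response list. MX1, an antiviral GTPase (chromosome 21, 41420304 to 41459214), stood at 2.45 ± 0.0592 CPM in wild type and 37.6 ± 11.6 CPM in the knockout, a log2 change of 3.94 (SE 0.25, edgeR adjusted p = 3.66e-08). IFI27 stood at 6.28 ± 2.56 and 122 ± 8.30 CPM, a log2 change of 4.26 (SE 0.30, adjusted p = 1.01e-07). SLC27A6, a fatty acid transport gene (chromosome 5, 128538013 to 129033642), fell from 18.5 ± 3.44 to 0.325 ± 0.226 CPM, a log2 change of -5.83 (SE 0.29, adjusted p = 6.35e-09). AREG, a ligand of the EGF receptor (chromosome 4, 74445134 to 74455009), fell from 164 ± 10.4 to 32.0 ± 0.29 CPM, a log2 change of -2.36 (SE 0.13, adjusted p = 1.30e-08).

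Of 39 interferon-response genes, 35 were higher in the knockout and none lower (35 adjusted over the list alone), with a median of 1.67, or 3.19-fold. Camera called this list at the preset correlation (adjusted p = 3.94e-86) but not with an estimated correlation (adjusted p = 0.057). The restriction factor BST2 rose by 3.16, IFI6 by 3.20 and IFIT1 by 3.54. Class I antigen presentation genes were higher in 9 of 21 cases (11 over the list alone, adjusted p = 0.34 with an estimated correlation), among them the immunoproteasome subunits PSMB8 (1.68) and PSMB9 (1.91), which overlap each other on opposite strands, and the transporter TAP2 (0.93).

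Estrogen-response genes were lower in 8 of 40 cases and higher in 1 (19 and 1 adjusted over the list alone), with a median of -0.34 and an adjusted p = 0.35 with an estimated correlation. Lower members were STC2 (-0.87), CELSR2 (-1.43) and EGR3 (-1.28). Of 26 luminal genes, 4 were lower (6 over the list alone, adjusted p = 0.50 with an estimated correlation), with the preset call ended without wild type replicate a2 (adjusted p = 0.111). E-cadherin, CDH1, changed by -0.76 and lost its call without wild type replicate a2 (-0.72, adjusted p = 0.0549) or knockout b2 (-0.65, adjusted p = 0.095). Immediate early genes were lower in 8 of 29 cases (12 lower and 1 higher over the list alone, adjusted p = 0.41 with an estimated correlation), such as KLF4 (-0.92) and the phosphatase gene DUSP4 (-0.66). Among 17 genes of the senescence secretory list, 5 were lower and 2 higher (7 and 3 over the list alone, adjusted p = 0.23 with an estimated correlation), with IGFBP5, which binds insulin-like growth factors, at -2.47, and the preset call ended with no filter on low counts (adjusted p = 0.0887). MUC5AC, a secreted mucin with close relatives, changed by -3.77, the glycosyltransferase gene GALNT5 by -3.81 and the retinoic acid hydroxylase gene CYP26B1 by -3.20. The gap junction gene GJA1 rose by 3.20.

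The cell-cycle lists moved little without the drug. The DNA replication list had 5 of 50 genes higher (3 adjusted over the list alone), a median of 0.12 and an adjusted p = 0.46 with an estimated correlation. Its preset call ended without wild type replicate a2 (adjusted p = 0.059). The mitosis list was not called by camera, with 1 gene higher and 1 lower of 50 (none over the list alone) and a median of 0.04, nor was the recombination list, with 2 of 32 higher (2 over the list alone). Camera did not call the RB and CDK list (adjusted p = 0.361), with 4 of 34 lower (4 over the list alone), RB1 among them, whereas fry gave it an adjusted p = 0.048 in the lower direction. Mitochondrially encoded genes were lower in 4 of 13 cases (10 over the list alone, adjusted p = 0.63 with an estimated correlation), with mitochondrial shares of 1.80 and 1.67 percent in wild type and 1.40 and 1.27 percent in the knockout. Lysosomal genes were lower in 4 of 35 cases (4 over the list alone, adjusted p = 0.56 with an estimated correlation), a preset call that ended without wild type replicate a2 (adjusted p = 0.133).

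edgeR called 692 genes higher and 1052 lower in the knockout under DMSO, together 10.5 percent of all genes tested, of which 250 and 187 changed at least 2-fold. The higher share of the calls was 39.7 percent, against 53.2 percent with upper quartile scaling and 51.6 percent with total counts, so the direction of the balance depends on the scaling. The counts became 251 and 291 without wild type replicate a2 under DMSO, 399 and 655 without knockout a2 under DMSO, 218 and 195 without knockout b2 under DMSO, 1200 and 1671 without knockout a2 under palbociclib and 1217 and 1647 without knockout b2 under palbociclib. Of 38 named genes called, 24 kept the call in every leave-out.

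**Figure D3:**
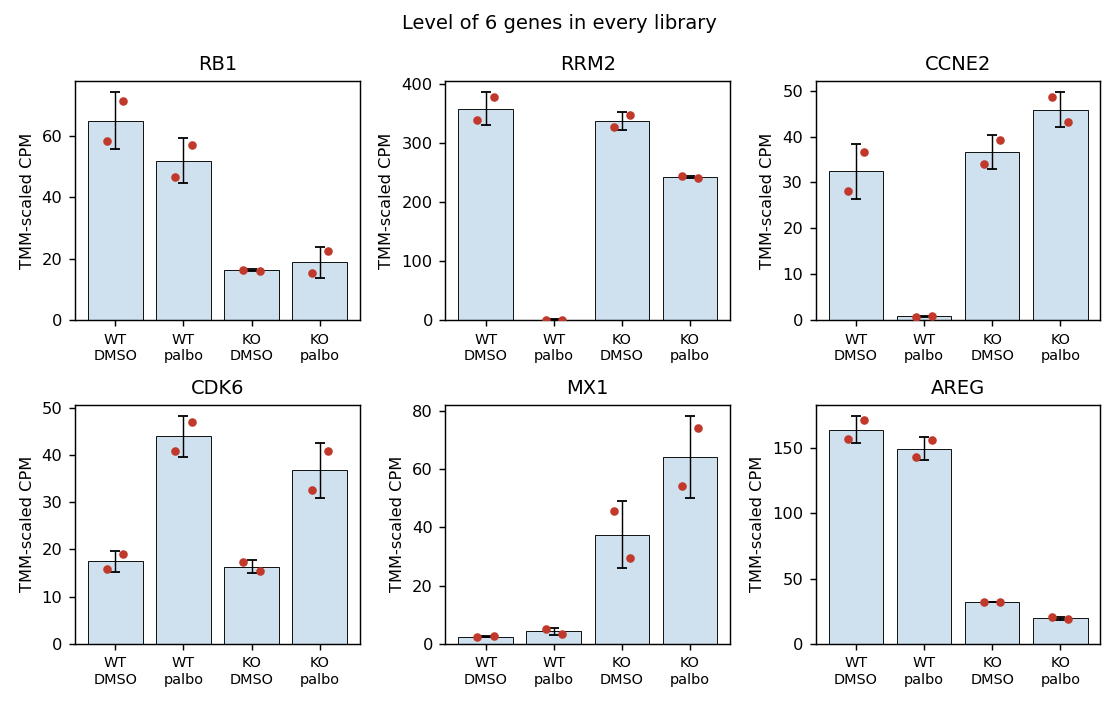
TMM-scaled CPM of 6 genes in the 8 libraries, 1 red point per library, with columns at the group mean and error bars of 1 SD (n = 2), for wild type (WT) and RB knockout (KO) cells under DMSO or palbociclib (palbo). RB1 lies between 46.8 and 71.6 CPM in the wild type libraries and between 15.3 and 22.5 CPM in the knockout libraries.

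Under palbociclib, transcripts of DNA synthesis and division were far higher in the knockout than in wild type. RRM2 stood at 0.643 ± 0.297 CPM in wild type and 242 ± 1.69 CPM in the knockout, a log2 change of 8.54 (SE 0.22, edgeR adjusted p = 1.56e-13). HMMR, a protein of the mitotic spindle, stood at 0.265 ± 0.085 and 32.0 ± 1.98 CPM (6.90, SE 0.26, adjusted p = 2.47e-12). IGFBP5 went the other way, at 1360 ± 78.5 CPM in wild type and 130 ± 26.3 CPM in the knockout (-3.38, SE 0.17, adjusted p = 1.06e-10), as did AREG at 150 ± 8.93 and 19.5 ± 1.20 CPM (-2.94, SE 0.13, adjusted p = 1.98e-11).

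All 50 DNA replication genes, all 50 mitosis genes and all 32 recombination genes were higher in the knockout, over all genes and over each list alone, with medians of 2.09, 4.70 and 2.37 and adjusted p-values of 0.0028, 0.0032 and 0.021 with an estimated correlation. In the RB and CDK list 19 of 34 were higher and 6 lower (20 and 6 adjusted over the list alone, adjusted p = 0.016 with an estimated correlation), with CCNE2 at 5.82, E2F7 at 4.72. Interferon-response genes were higher in 33 of 39 cases (34 over the list alone), with a median of 1.42 and an adjusted p = 0.34 with an estimated correlation, including MX1 (3.92) and BST2 (2.10).

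Estrogen-response genes were lower in 22 of 40 cases and higher in 5 (23 and 5 adjusted over the list alone, adjusted p = 0.46 with an estimated correlation), among them the trefoil factor TFF1 (-1.50), XBP1 (-1.10) and STC2 (-1.23). Luminal genes were lower in 14 of 26 cases and higher in 1 (15 and 2 over the list alone, adjusted p = 0.42 with an estimated correlation), such as CDH1 (-0.95) and the receptor ERBB3 (-0.91). Lysosomal genes were lower in 20 of 35 cases (23 over the list alone, adjusted p = 0.34 with an estimated correlation), including the protease genes CTSD (-0.87) and TPP1 (-0.80). Immediate early genes were lower in 10 of 29 cases and higher in 1 (10 and 2 over the list alone, adjusted p = 0.59 with an estimated correlation). Mitochondrially encoded genes were lower in 12 of 13 cases (12 over the list alone, adjusted p = 0.63 with an estimated correlation), among them MT-ATP6 (-0.90) and MT-CO3 (-0.75), which overlap on the same strand. The mitochondrial share was 2.54 and 3.15 percent in wild type and 1.70 and 1.89 percent in the knockout, and so moved with each of these groups.

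edgeR called 2878 genes higher and 2435 lower in the knockout under palbociclib, together 32 percent of all genes tested, of which 1242 and 453 differed at least 2-fold. The higher share of the calls was 54.2 percent, against 68.3 percent with total counts alone, which shifted the median of all genes by 0.10. The lower count was 1433 and 1366 without wild type replicate a2 or b2 under palbociclib. All 33 named genes called here kept the call in every leave-out.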

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

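The differences between genotypes given first were tested as planned, whereas all tests of explanations in the last 3 paragraphs were chosen only after the result was seen. A difference between the effects of palbociclib in wild type and in knockout cells, wild type minus knockout, was called for 179 genes in the higher and 894 genes in the lower direction. Among the fixed lists, the median difference was -0.59 for the RB and CDK list, -1.93 for DNA replication, -4.64 for mitosis, -2.23 for homologous recombination, 0.35 for the interferon response, 0.22 for lysosomal genes and 0.47 for ribosomal proteins. Camera called the last 3 lists at the preset correlation but not with an estimated correlation (adjusted p = 0.80, 0.46 and 0.69), fry called the lysosomal list alone of these (adjusted p = 0.04), and they had 4 of 39, 0 of 35 and 0 of 40 genes called.

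Of 92 named genes, 45 differed, the largest adjusted p being 0.041. Some of the 92 were named because of this same difference, so the share is raised by the selection. Over all genes tested, 6.46 percent were called. The mitotic genes were KIF20A (-8.27), KIF4A (-6.94), BIRC5 (-6.63), AURKB (-6.53), KIF2C (-6.03), PLK1 (-5.97), PTTG1 (-5.15) and MYBL2 (-3.18). The genes of DNA synthesis and repair were RRM2 (-8.62), FAM111B (-6.65), MCM10 (-5.94), TK1 (-4.62), EXO1 (-4.46), CDC45 (-4.27), MND1 (-4.07), ORC1 (-3.53), FANCI (-3.23), RAD51 (-3.13), FANCD2 (-2.20), MCM7 (-1.95) and DDB2 (-1.01). Genes of the RB and CDK list were CCNE2 (-5.64), E2F7 (-4.82), E2F8 (-4.44), RBL1 (-2.59), E2F1 (-2.44), CCNE1 (-1.74) and CDK4 (-0.65). More negative log2 changes in wild type were also called for HIST1H2BJ (-2.36), PHGDH (-2.09), SLC7A5 (-0.98), ENO2 (-0.93) and FADS1 (-0.82). Higher log2 changes in wild type were called for UGT2B15 (1.73), ZNF233 (1.69), IFIT1 (1.57), FAXDC2 (1.52), BBS12 (1.5), HIST1H4H (1.27), TMEM140 (1.12), BST2 (1.06), OAS1 (0.96), TM7SF2 (0.95), IGFBP5 (0.90) and XBP1 (0.74). Leave-outs were run for 27 of the called genes, and 6 lost the call in at least 1 of them. The highest adjusted p was 0.231 for BST2, 0.163 for OAS1 and 0.0508 for FADS1, each without wild type replicate a2 under palbociclib, and OAS1 also lost the call with total counts (adjusted p = 0.0513). The highest was 0.145 for XBP1 and 0.15 for IGFBP5 without knockout a2 under DMSO, and 0.0862 for IFIT1 without wild type b2 under DMSO.

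After palbociclib in the knockout, 131 cell-cycle genes stood a median of 23.7 percent lower, with 11 of 50 replication, 18 of 50 mitosis and 9 of 32 recombination genes called and list adjusted p-values of 0.035, 0.12 and 0.23 with an estimated correlation. RB-positive cells of the knockout line itself would lower every gene that fell at least 16-fold in wild type by about the same amount. This holds only if they carried each transcript at the level of the other cells, which was not measured. Those 50 genes ranged from -1.05 to -0.05 around a common -0.50. Their heterogeneity was 2.02 per degree of freedom, against a bound of 1.74 and a highest value of 1.35 in 40 simulations. The simulations gave all 50 genes 1 common fall, so the value goes against that, but not against such cells with unequal levels. A Spearman's rho of 0.569 linked wild type and knockout changes across the cell-cycle genes. Such cells could give it, but so could a weak effect of the drug on the same genes, so it favours neither. Named genes outside the cell-cycle lists that fell at least 16-fold in wild type were looked at after their values were seen. In the knockout they changed by -0.82 (E2F8), -0.37 (E2F7), -0.11 (FAM111B) and 0.32 (CCNE2, not called by edgeR, adjusted p = 0.232). RB-positive cells of the knockout line stay open as an explanation. Wild type cells among the knockout cells would need a share of at least 20.5 percent. Of 8898 genes with at least 10 CPM in both wild type groups, only 2 lay below that by a margin of about 2 standard errors in both conditions. The requirement of 10 such genes was a choice made after the result was seen, so the count decides little. By that count this explanation stays open. SLC27A6 (1.76 and 1.84 percent of wild type) and MUC5AC (7.34 and 6.07 percent) lay far below it. If such cells expressed these genes as the wild type libraries did, that share would have kept both at 20.5 percent or more. These 2 genes therefore go against such a share, on a premise that was not tested. An effect of the drug that does not need RB stays open and untested.

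In the knockout under DMSO, 35 of 39 interferon-response genes were higher (list adjusted p = 0.057 with an estimated correlation), the list's summed level going from 647 ± 2.33 to 1970 ± 278 CPM. Immune cells in the knockout cultures would bring their own transcripts, but 16 immune markers summed to 1.78 ± 0.357 CPM in wild type and 1.78 ± 0.469 CPM in the knockout, a change of 0.00225 CPM, and PTPRC had 0 counts, which argues against them. A difference between the 2 lines other than RB cannot be told apart from the loss of RB, because the labels name only 1 knockout line. The loss of RB stays among the open explanations, as untested.

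Of 4 entries for signal recognition particle RNA, 3 were called lower after palbociclib in the knockout and RN7SL832P was not (-0.90, adjusted p = 0.196). RN7SL2 had a log2 change of -1.95 (adjusted p = 0.00532), a call lost without knockout replicate b2 under DMSO (-1.51, adjusted p = 0.0619). In libraries selected for poly(A) tails, less carry-over of short RNAs without such tails would lower other such RNAs as well. Whether these libraries were so selected is not stated. Of 21 other entries, 20 were lower in the knockout, with a median of -2.13, and the median in wild type was -1.23. These entries were put in 4 groups, of which the U RNA and small nucleolar groups hold unlike RNAs. Many entries are copies that may share reads, and the RNU1 and SNORD3 copies lay under 1 CPM. The entries are therefore not 21 separate observations, and their bootstrap SE of 0.22 does not allow for shared reads. The median was below 0 in 4 of the 4 families in the knockout. The signal recognition particle entries had a median of -2 in the knockout and -0.477 in wild type, so in wild type they fell less than the other entries. That technical explanation fits most of the knockout values if the libraries were selected for poly(A) tails. No biological explanation was tested.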

How the results depend on the processing

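Every alternative named here was planned, and the cause of a change was not tested unless stated. Of 203 called results of named genes, 151 kept their call and direction in all alternatives and 194 in all but the leave-outs; of 56 called list tests, 13 did so. With an estimated correlation 13 list tests were called. No named gene reversed. With the replicate letter as a block, which links libraries by a number alone, calls were 2203 and 2447 (wild type, palbociclib), 465 and 179 (knockout, palbociclib), 162 and 882 (difference), 651 and 932 (knockout, DMSO) and 2841 and 2380 (knockout, palbociclib against wild type), and among named genes only KIF20A in the knockout, chosen after its values were seen, lost its call (adjusted p = 0.0402 to 0.0538). KIF20A also lost it with total counts (adjusted p = 0.0612), with only the 4 libraries compared (adjusted p = 0.0747) and in all 8 leave-outs. A minimum log2 change of 1, which by its construction keeps fewer genes, left 532 and 970, 119 and 32, 72 and 650, 250 and 187, and 1242 and 453 genes in the same order. Fits of only the 4 libraries compared gave 219 and 80 genes for palbociclib in the knockout and 1247 and 1638 for the knockout under DMSO. With no filter, 393 genes were lower after palbociclib in the knockout and 1076 were higher in the knockout under DMSO. That fit also gave 400 genes with a higher log2 change after palbociclib in wild type than in the knockout. Total counts gave 111 genes with a higher log2 change after palbociclib in wild type than in the knockout. They gave 687 genes lower in the knockout under DMSO. Pearson's r between the drug's effects was 0.501 for genes with a mean of 2 CPM. In the leave-outs, where a group's lone library is assumed to vary like the other groups, counts ranged from 1233 to 2746 higher and 1603 to 2918 lower for palbociclib in wild type, 104 to 1089 and 19 to 485 for palbociclib in the knockout, and 56 to 473 and 663 to 1275 for the difference. For the knockout they ranged from 218 to 1217 higher and 195 to 1671 lower under DMSO, and from 2037 to 2912 and 1366 to 2518 under palbociclib. RB1 ranged from -0.47 to -0.17 for palbociclib in wild type, from -0.09 (without knockout replicate b2 under palbociclib) to 0.50 (without a2) in the knockout, from -0.83 to -0.24 for the difference, from -2.14 to -1.85 for the knockout under DMSO and from -1.77 to -1.17 under palbociclib. The ribosomal protein list in the knockout, at -0.13, reversed to 0.10 (adjusted p = 0.108) without knockout replicate b2 under palbociclib and was -0.38 without replicate a2. Depth limits genes near the floor: the smallest count over the 8 libraries was 6 for KIF20A, 12 for RRM2 and 5 for SLC27A6.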

Other observations

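The lists were fixed before the data were examined, and the genes below were named by the same rule, with no test chosen after its result was seen. Hypoxia-response genes were higher after palbociclib in wild type in 8 of 20 cases and lower in none (8 adjusted over the list alone, median 0.41, adjusted p = 0.34 with an estimated correlation). In the knockout 2 were higher after palbociclib (3 over the list alone, median 0.22, adjusted p = 0.23 with an estimated correlation). DDIT4, an inhibitor of mTORC1 signalling, rose from 70.1 to 167 CPM in wild type (log2 change 1.25) and from 87.8 to 165 CPM in the knockout (0.91), and NDRG1 rose by 0.75 in wild type. Within the knockout, basal epithelial markers were higher after palbociclib than under DMSO in 6 of 12 cases (6 over the list alone, median 0.64, adjusted p = 0.24 with an estimated correlation), among them the laminin chain LAMC2 (0.80). Mesenchymal markers were likewise higher after palbociclib in 4 of 9 cases (6 higher and 1 lower over the list alone, median 0.67, adjusted p = 0.11 with an estimated correlation). Both lists were fixed as checks for other cell types, with 16 and 20 members. The basal keratins KRT5, KRT6A, KRT6B and KRT14 were not tested and reached at most 0.266 CPM in any library. The untested mesenchymal markers reached at most 0.4 CPM. The tested members of these lists therefore do not show a basal or mesenchymal cell type. For palbociclib in wild type camera called neither list (adjusted p = 0.0609 and 0.199), though fry did in the higher direction (adjusted p = 0.039 and 0.028), and camera called the basal list without wild type replicate a2 under DMSO (adjusted p = 0.0273) or a2 under palbociclib (adjusted p = 0.0435). There 5 of 12 and 5 of 9 genes were higher and 1 of each lower (5 and 1, and 5 and 2, over the list alone). COL3A1, a fibrillar collagen gene, stood at 9.35 CPM in wild type and 37.8 CPM in the knockout under DMSO (2.02).

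Other lists held genes that moved apart. Camera did not call the targets of p53 after palbociclib in wild type (adjusted p = 0.864), while fry did in the lower direction (adjusted p = 0.024), with 4 higher and 8 lower of 32 (4 and 8 over the list alone): TP53INP1 rose by 1.57 and DDB2, which recognises damage from ultraviolet light, fell by 1.51. Replication-dependent histone genes, whose reads may be shared between copies, were 9 higher and 8 lower of 28 (9 and 9 over the list alone), with a median of 0.06 and a mean of -0.29. Genes of the unfolded protein and ATF4 response were 4 higher and 8 lower of 29 in wild type (4 and 10 over the list alone). Camera did not call that list (adjusted p = 0.535), while fry did in the lower direction (adjusted p = 0.039), and PHGDH went from 37.9 to 6.31 CPM. Ribosomal protein genes were higher in wild type after palbociclib in 9 of 40 cases (8 over the list alone, adjusted p = 0.83 with an estimated correlation), with RPL3 at 0.53, a call lost without wild type replicate b2 under DMSO (adjusted p = 0.0515) or a2 under palbociclib (adjusted p = 0.0651). Camera called the lists of cholesterol synthesis, fatty acid synthesis and glycolysis in no comparison. fry, which does not compare a list with other genes, called cholesterol synthesis lower in the knockout under DMSO (adjusted p = 0.047) and under palbociclib (adjusted p = 0.04). Of 16 immune markers, 3 were expressed enough to be tested, so that list was not tested.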
